A study of Mus musculus with 2 samples.

How the data were processed

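The data were peak lists from ATAC-seq of limbs of mouse embryos at 14.5 days of development, with 2 biological replicates in 1 group. Per the labels, 24 embryos were pooled for replicate 1 and 34 for replicate 2, both pools held both sexes, and library fragments were selected at 200–750 bp. Each replicate had 3 lists and the series 6. Per the deposited README, the lists of a replicate were derived from that library's alignments, those of the series from both libraries' alignments, and the thresholded lists also from 1 further file whose type is not stated. The build was mm10 (GRCm38), per the labels and the README. The aligner and the peak caller were not given in the sources used here. The labels name lists past an irreproducible discovery rate (IDR) threshold, ranked lists, pseudoreplicated lists of each replicate and a replicated list without an IDR threshold. The read depth was unknown, since the lists hold no counts.

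The authors' signal is a measure of enrichment per peak summit whose normalization was not stated, and it was compared only within its own list. The deposited score, at most 1000, started at 540 in the IDR lists and was used only to relate lists to each other. All 47946 summits of the conservative list lay in one ranked list at a score of at least 540, and all 50820 summits of the other IDR list of the series in the other ranked list. The ranked lists hold 20 columns, of which 2 give values per sample without naming the replicate, and these were not used.

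Summits on the 21 chromosomes were kept, and overlapping peaks of a list were merged into regions, each with the signal and summit of its strongest peak. The conservative list was used for genes and motifs, and the lists of the replicates gave the spread. A region of one replicate counted as shared if it overlapped a region of the other by at least 50% of the shorter of both, and chance was estimated from 100 circular shifts along each chromosome. Shares have Wilson 95% intervals. A promoter region had its summit within 1 kb of any start site of a protein-coding transcript in GENCODE M21 (21829 genes), and all other regions were distal. It was counted for every gene with such a start site, so neighbouring genes can share a region and a region can lie inside a gene. Gene lists were written from general knowledge before the data were examined, as were the motifs, the tests and most alternatives. The 24 lists were limb patterning, the HoxA, HoxB, HoxC and HoxD clusters, BMP and TGF-beta signalling, WNT signalling, retinoic acid, chondrocyte, osteoblast, joint and tendon, skeletal muscle, epidermis, endothelium, erythroid, myeloid, lymphoid, Schwann cell and melanoblast, neuron, hepatocyte, cardiomyocyte, germ cell and pluripotency, housekeeping and chemosensory receptors.

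List members were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. For distal regions, each was given to the gene with the nearest start site within 100 kb, and the mean per member was compared with 10000 random lists matched on 10 classes of the length of DNA nearest to the gene's start sites (two-sided permutation test, in which 0.0002 is the smallest p-value these lists can give). Promoters of the 4 Hox clusters were compared in 6 pairs by Fisher's exact test. The 22 motifs were searched as consensus sequences on both strands within 100 bp of distal summits and in windows 1 kb to each side, and ratios are of the share at summits to the mean share of both flanks. Summits that differed from 1 flank drawn at random were compared by a two-sided exact binomial test adjusted over the motifs. Up to 20 distinct shuffles of each motif were searched in the same way, at the summits of the conservative list only.

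Named genes were chosen by rule: in each list with at least 5 members, the 2 with the highest promoter signal in the conservative list among those open in both replicates, the 2 with most distal regions and, for lists of cell types and other tissues, the first 2 members without a promoter region in either replicate. The rule also covers, across the genome the 10 genes with most distal regions, the 5 strongest distal regions and all genes of the Hox clusters. Sequence matches were searched with BLAST (E-value 1e-10).

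Alternatives covered the peak list, the stronger 50% of regions by signal, each replicate alone, unmerged peaks, the overlap rule, equal list sizes, windows of 500 bp and 2.5 kb, 1 start site per gene, matching on the CpG content of the 1 kb around the start site, assignment within 50 kb or 1 Mb, no matching on stretch length, motif windows of 50 bp and flanks 2 kb away. Peaks on unplaced scaffolds were left out of regions. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyfaidx 0.9.0.4 and matplotlib 3.10.9, and BLAST was version 2.17.0. The methods were tested on simulated data in 50 draws of 21829 genes. Lists of 25 members with 90% open against 50% of other genes were called in 98.7% of cases and lists without a planted difference in 1.53%. Distal regions were planted at 3 times the larger of the gene's own rate and the mean rate, a difference of 3-fold or more. It was called in 74.7% of cases, against 0.706% without one, and the power at exactly 3-fold was not measured. A CTCF motif planted in 10% of 5000 windows was found in 10.2% of them, and no other motif was called. Simulated summits and flanks had the same base composition, so false calls from a difference in GC content could not arise there.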

Results

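Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in limbs of mouse embryos at 14.5 days of development. At this stage the limb holds cartilage, forming tendon and muscle, vessels, nerves and skin. Both libraries belonged to 1 group and were biological replicates pooled from embryos of both sexes, 24 embryos in replicate 1 and 34 in replicate 2. The labels gave no contrast between conditions, so the comparisons were between the replicates, between groups of genes, between the Hox clusters and between open regions and their flanks. The data were lists of peaks. Their read depth was unknown, intervals on shares cover counting error only, and p-values over genes or regions describe these libraries, since genes are not replicates. In the lists past an irreproducible discovery rate (IDR) threshold, replicate 1 had 41240 summits, which merged into 17847 regions covering 14.9 Mb (median width 829 bp), and replicate 2 had 30696 summits in 13235 regions covering 11.2 Mb (median width 841 bp). The smaller of the IDR lists derived from both libraries, called the conservative list below after its label, had 47946 summits in 19629 regions covering 17.6 Mb, or 0.646% of the genome, and was used for genes and motifs unless another list is named. It held more regions than either replicate's list. Of its regions 79.9% lay on a region of replicate 1's IDR list and 64.9% on one of replicate 2's, so a region need not be in both of these lists. Absence from such a list does not show that the library had no peak there. A peak's signal is the authors' own value without a unit (median 8.76 and highest 56.0 in the conservative list), and coordinates are on GRCm38 (mm10).

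How far the open regions recurred between the replicates was asked first. Promoter regions, with their strongest summit within 1 kb of a protein-coding start site, recurred more often than distal ones in both directions. Of the regions of replicate 1, 86.3% of those at promoters and 42.4% of the distal ones lay on a region of replicate 2, and of those of replicate 2 the shares found in replicate 1 were 97.7% and 83.2%. The promoters of Tgfbr1 (a TGF-beta receptor), Sox9 (the main regulator of cartilage formation) and Myl4 (a myosin light chain) were open in both replicates. In the IDR lists the promoter of Hand2, which acts upstream of Sonic hedgehog in the posterior limb bud, was open in replicate 1 only. That of Erg, an endothelial transcription factor, was open in replicate 2 only. Both had a region in the replicated list without an IDR threshold, so the absences hold for the thresholded lists only. In total 12322 of the 17847 regions of replicate 1 were shared (69.0%, Wilson 95% interval 68.4 to 69.7), as were 12407 of the 13235 regions of replicate 2 (93.7%, 93.3 to 94.1). Circular shifts of the regions along the chromosomes gave mean shares of 0.531% and 0.717%, with 0.740% and 0.937% as the highest of 100 shifts. The share was mostly higher among regions with a stronger signal, although the second-weakest 10% of replicate 1 (28.6%) lay below the weakest. It was 30.0% in the weakest 10% of the regions of replicate 1 and 99.9% in the strongest, and 76.3% and 100% in replicate 2. Promoter regions made up 37.8% of the weakest 10% of replicate 1 and 93.3% of the strongest, so their higher recurrence partly went with signal. In the weakest 10% of replicate 1, 42.1% of promoter and 22.6% of distal regions were shared, and in the strongest 99.9% and 100%. In replicate 2 the shares were 83.2% and 69.6% in the weakest and 100% for both in the strongest. With the same number of strongest regions from both replicates, 82.3% and 83.1% were shared.

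**Figure D1:**
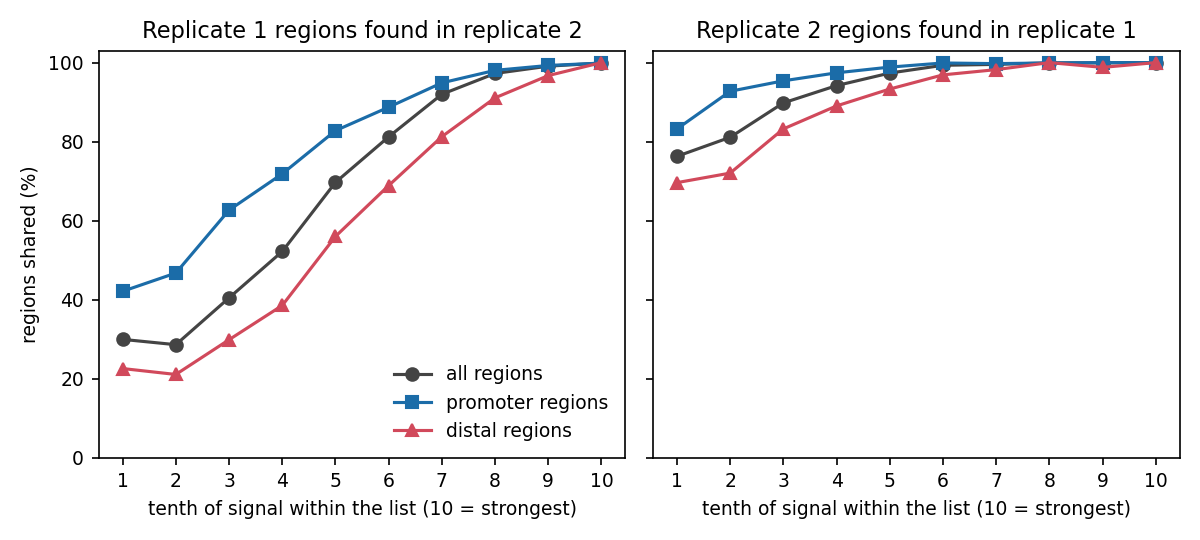
Share of the regions of each replicate found in the other (vertical axis, percent) by signal rank within the list (horizontal axis, steps of 10% of the regions, strongest on the right), with points for all, promoter and distal regions. Of the strongest regions 99.9% and 100% were shared, and of the weakest 30.0% and 76.3%.

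Most open regions of the conservative list lay at the starts of protein-coding genes. Of its 19629 regions, 57.2% were promoter regions, although the windows within 1 kb of a start site make up 2.37% of the genome, a 24.1-fold enrichment. The share was 66.8% ± 8.50 (SD, n = 2) over the replicates (60.8% in replicate 1, 72.8% in replicate 2) and differed less at equal list size, with 70.4% among the 13235 strongest regions of replicate 1. Of the 21829 protein-coding genes, 11658 (53.4%) had a promoter region in the conservative list, 11320 in replicate 1 and 10230 in replicate 2. A region counted for every gene with a start site within 1 kb of its summit, so the 11220 promoter regions gave 11658 genes. The signal named for a gene can therefore be that of a start shared with a neighbour, which was not tested. With 1 start site per gene 10874 genes had a promoter region. Of the unmerged summits 65.2% lay within 1 kb of a start site. Without an IDR threshold the list replicated in both libraries had 56277 regions, of which 26.7% were at promoters, and 13833 genes had a promoter region.

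Genes of BMP and TGF-beta signalling, a pathway that patterns the limb and starts its cartilage, had an open promoter more often than other genes. Of the 24 members 20 did (83.3% against 53.4% of other genes; two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 24 gene lists, adjusted p = 0.00813). The share over the replicates was 68.8% ± 2.95 (SD, n = 2). The highest signals of the list were at Tgfbr1 (15.4 at 4:47352497–47353683) and Bambi, a pseudoreceptor that dampens the pathway (15.3 at 18:3507141–3508371). All 20 housekeeping genes had a promoter region (Fisher's adjusted p = 3.01e-05). They were led by Rplp0, a ribosomal protein (16.0), and B2m, the light chain of MHC class I (14.2). Limb patterning genes did not differ from other genes, with 19 of 35 open (54.3%, Fisher's adjusted p = 1), nor did those of WNT signalling (14 of 25, 56.0%, 0.964) or retinoic acid (8 of 16, 50%, 0.964). Replicate 2 alone had lower shares, with 34.3% of limb patterning, 32.0% of WNT and 31.2% of retinoic acid genes open, against 45.7%, 52.0% and 50% in replicate 1. Among the patterning genes the highest signals were at the T-box gene Tbx3 (10.96 at 5:119670031–119671167) and the homeobox gene Msx2 (9.71 at 13:53472347–53473183). Lmx1b, which specifies dorsal limb fate, was open in the IDR list of replicate 1 but not of replicate 2. It had a region in the replicated list without an IDR threshold. Lgr4, a receptor for R-spondins, led the WNT list (15.8), followed by the WNT receptor Fzd7 (12.1), and the retinoic acid receptors Rarb (9.40) and Rara (8.54) led theirs. The BMP call was lost in each replicate's own list (exact adjusted p = 0.103 for replicate 2 and 0.109 for replicate 1), with a window of 500 bp (0.114) and against random lists matched on promoter CpG content (0.866), which also ended the housekeeping call (0.0950). In the stronger 50% of regions limb patterning (−26.3 points, exact adjusted p = 0.00361) and retinoic acid genes (−34.3 points, 0.00705) were open less often than other genes, and the BMP list (−11.4 points, 0.316) did not pass. Limb patterning (32 of 35, 91.4%, exact adjusted p = 0.00118) and WNT genes (23 of 25, 92.0%, 0.00649) were open more often than other genes without an IDR threshold. Against lists matched on CpG content both were open less often (permutation test, adjusted p = 0.00343 and 0.0470).

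In the conservative list, markers of the limb's epidermis and endothelium had open promoters less often than other genes, and no difference from other genes was found for markers of its connective tissues and muscle. Chondrocyte markers were open in 12 of 28 cases (42.9%, Fisher's adjusted p = 0.485), osteoblast markers in 7 of 18 (38.9%, 0.365), joint and tendon markers in 11 of 21 (52.4%, 1) and skeletal muscle markers in 17 of 32 (53.1%, 1). The highest signals were at Col11a1, a cartilage collagen (14.1 at 3:114030027–114030775), and Sox9 (8.73 at 11:112781385–112782699) among chondrocyte markers. Among osteoblast markers they were at Smpd3, a sphingomyelinase of mineralising bone (18.7), and Col1a2, a chain of type I collagen (14.6). Among joint and tendon markers they were at the transcription factor genes Egr1 (12.7) and Pitx2 (12.2), and among muscle markers at the myosin light chain genes Myl4 (13.9 at 11:104549985–104551080) and Mylpf (12.3 at 7:127208294–127209491). No promoter region was found in either replicate at Sox5 and Sox6, the partners of Sox9, at Runx2 and Sp7, both needed for osteoblasts, at Gdf5 and Mkx, regulators of joint and tendon, or at the myogenic factors Myf5 and Myf6. The conservative list held a region at Sox5, and the list without an IDR threshold held regions at Sox5, Runx2, Gdf5, Mkx and Myf5. Of the epidermal markers 3 of 26 were open (11.5% against 53.5%, Fisher's adjusted p = 7.34e-05). The signal was 9.72 at Klf4 and 9.35 at Krt10, a keratin of differentiating skin. The Krt10 region (11:99385844–99386782) lay at a transcript start inside the gene (11:99385254–99389364, minus strand), not at its 5' end. The same held for the conservative list's regions at Pitx2, Ets1 and Sox5, and for those at Rarb and Rara above. Such a position is not listed for every region named. No region lay in either replicate at Trp63 and Krt5, genes of the basal layer, although Trp63 had one without an IDR threshold. Endothelial markers were open in 5 of 21 cases (23.8%, Fisher's adjusted p = 0.0169), with the highest signals at Ets1 (14.8) and the lymphatic regulator Prox1 (8.37) and no region in either replicate at Pecam1 and Cdh5, which encode junction proteins. The epidermal (16 of 26, exact adjusted p = 0.841) and endothelial lists (12 of 21, 0.744) no longer differed from other genes without an IDR threshold, where the muscle list was open more often (27 of 32, 0.0340), and the endothelial call was also lost with a window of 2.5 kb (0.0514). In replicates 1 and 2 alone the shares were 37.5% each for muscle markers, 44.4% and 27.8% for osteoblast, 14.3% and 19.05% for endothelial and 7.69% each for epidermal markers. In the replicates' own lists 6 of 28 chondrocyte markers were open in each and the list was open less often than other genes (exact adjusted p = 0.00406 for replicate 1 and 0.0147 for replicate 2). In the stronger 50% of regions both the chondrocyte (−37.0 points, exact adjusted p = 0.000125) and the muscle list (−34.3 points, 0.000125) lay below other genes.

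Blood cell markers and markers of other tissues were open less often than other genes, apart from those of Schwann cells and melanoblasts. Erythroid markers were open in 1 of 19 cases (5.26%, Fisher's adjusted p = 8.60e-05), myeloid in 1 of 17 (5.88%, 0.000280) and lymphoid in 0 of 12 (0.000358). No promoter region lay in either replicate at the erythroid factors Gata1 and Klf1, the myeloid factor Spi1 and the receptor Csf1r, or the T-cell receptor chains Cd3d and Cd3e. The open myeloid promoter was that of Irf8 (8.31). Schwann cell and melanoblast markers were open in 7 of 16 cases (43.8%, Fisher's adjusted p = 0.618). Their highest signals were at Mitf, the regulator of melanocyte fate (16.1 at 6:97806756–97807449), and Mpz, a myelin protein (15.1 at 1:171150236–171151225), and no region lay at the neural crest factors Sox10 and Foxd3. Neuronal markers were open in 7 of 24 cases (29.2%, Fisher's adjusted p = 0.0420) and in 20.8% and 16.7% in replicates 1 and 2, led by the synaptic vesicle genes Syn1 (12.3) and Syt1 (11.6), with none at Rbfox3 and Gad1. Hepatocyte markers were open in 0 of 21 cases (Fisher's adjusted p = 1.29e-06), including the serum proteins Alb and Afp. Cardiomyocyte markers were open in 3 of 14 cases (21.4%, Fisher's adjusted p = 0.0483), among them the ion channel genes Hcn4 (8.48) and Ryr2 (7.18) but not the cardiac factors Nkx2-5 and Gata4. Of the germ cell and pluripotency markers 1 of 16 was open (6.25%, exact adjusted p = 0.000416), the germ cell gene Dazl (12.1), but not Pou5f1 and Nanog. Of the genes named here as without a region, Cd3d, Foxd3, Gad1, Gata4 and Pou5f1 had one without an IDR threshold. Of 1463 chemosensory receptor genes 1 had a promoter region, the vomeronasal receptor Vmn1r4 (16.6), against 57.2% of other genes. Against random lists matched on promoter CpG content the erythroid (permutation test, adjusted p = 0.0949), myeloid (0.745), lymphoid (0.758), hepatocyte (0.0558) and cardiomyocyte (0.288) calls were lost, and those of neuron, germ cell and chemosensory lists were not (0.000960 each). The neuronal and cardiomyocyte calls were also lost in the other IDR list (0.0772 and 0.107), with a window of 2.5 kb (0.174 and 0.110) and without an IDR threshold (0.841 and 0.270), and the cardiomyocyte call further with 1 start site per gene (0.0917) and in replicate 2 alone (0.103).

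**Figure D2:**
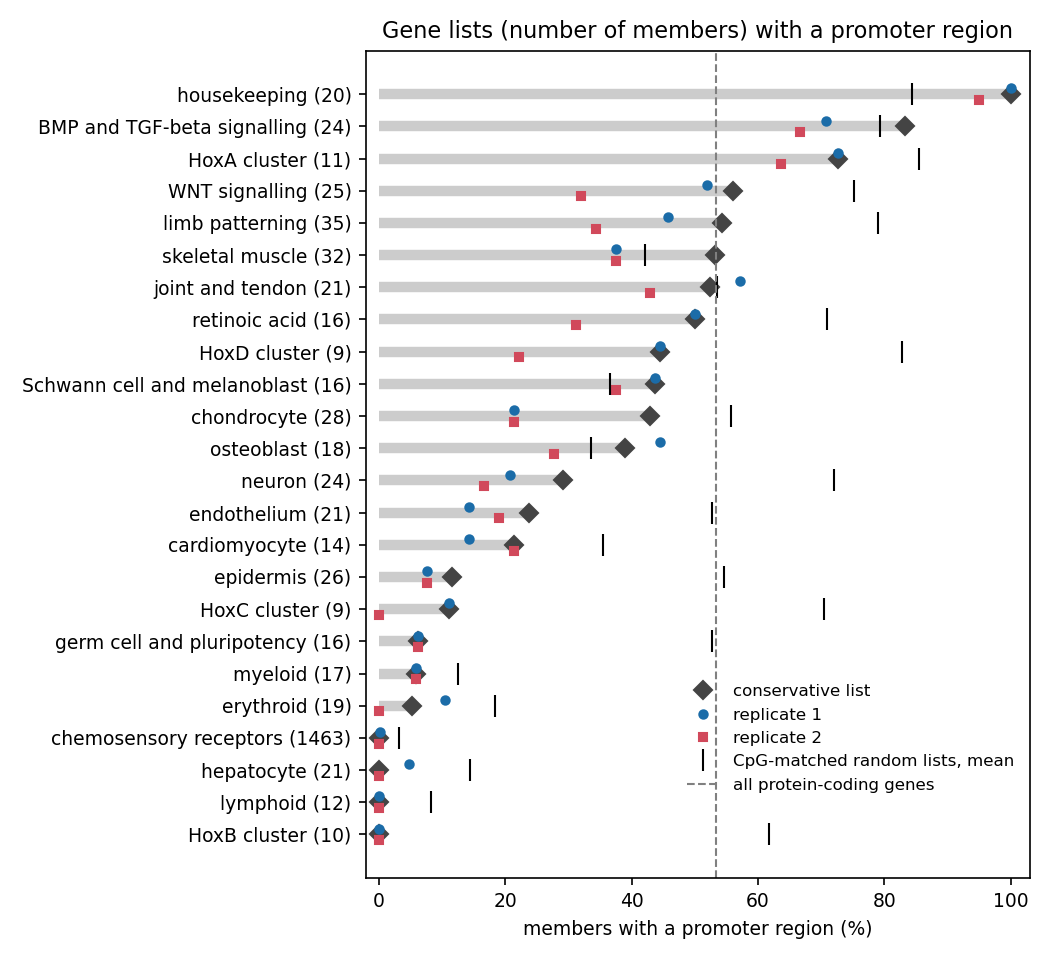
Share of the members of each gene list with a promoter region (percent; bars and diamonds, conservative list; circles and squares, replicates 1 and 2), with ticks at the mean of random lists matched on CpG content and a dashed line at the share of all protein-coding genes (53.4%). Housekeeping genes (100%) and BMP and TGF-beta genes (83.3%) lay above the line, and the HoxB cluster, lymphoid and hepatocyte lists had no open promoter in the conservative list.

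The 4 Hox clusters, whose genes set position along the body and limb axes, differed in how many of their promoters were open. In the HoxA cluster (6:52155590–52260880) 8 of 11 genes had a promoter region (Hoxa1, Hoxa3, Hoxa4, Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13), with the highest signal at Hoxa13 (7.75 at 6:52260379–52261423), a regulator of the hand and foot plate. In the HoxD cluster (2:74668310–74765142) 4 of 9 were open, all at its posterior end (Hoxd10, Hoxd11, Hoxd12 and Hoxd13), with the highest signal at Hoxd13 (8.07 at 2:74667530–74668803), a gene of digit formation. None of the 10 HoxB genes (11:96194316–96368256) had a promoter region in the conservative list or in either replicate. In the HoxC cluster (15:102921103–103036852) 1 of 9 did, Hoxc5, whose region was absent from both replicates' own lists, and the list of replicate 1 held a region at Hoxc10. The HoxB (Fisher's adjusted p = 0.00128) and HoxC (0.0305) lists were open less often than other genes and the HoxA (0.365) and HoxD (0.937) lists did not differ from them. Between clusters, HoxA exceeded HoxB (Fisher's exact test, adjusted p = 0.00619 over 6 pairs) and HoxC (0.0293), and the other pairs did not pass (HoxB against HoxD 0.0650, HoxA against HoxD 0.434, HoxC against HoxD 0.434, HoxB against HoxC 0.474). These tests take the genes of a cluster as independent, although they are neighbours. Regions covered 7.53% of the HoxA cluster (5.63% in replicate 1, 4.65% in replicate 2), 3.14% of HoxD (2.31% and 1.20%), 0.943% of HoxC (0.809% and 0) and 0.141% of HoxB (0.142% and 0). In the IDR list of replicate 2 only Hoxd10 and Hoxd13 were open in the HoxD cluster, although Hoxd11 and Hoxd12 had a region without an IDR threshold. Promoters of Hoxa5, Hoxb4, Hoxb9, Hoxb13, Hoxc4, Hoxc10, Hoxc13, Hoxd1, Hoxd3, Hoxd8 and Hoxd9 were open as well without an IDR threshold, where no pair of clusters passed (HoxA against HoxB 0.0899) and the HoxB (0.0814) and HoxC (0.404) calls were lost. In the stronger 50% of regions the HoxA (−40.5 points, 0.00705) and HoxD lists (0.0180) were also open less often than other genes, as was HoxD against lists matched on CpG content (0.0341).

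**Figure D3:**
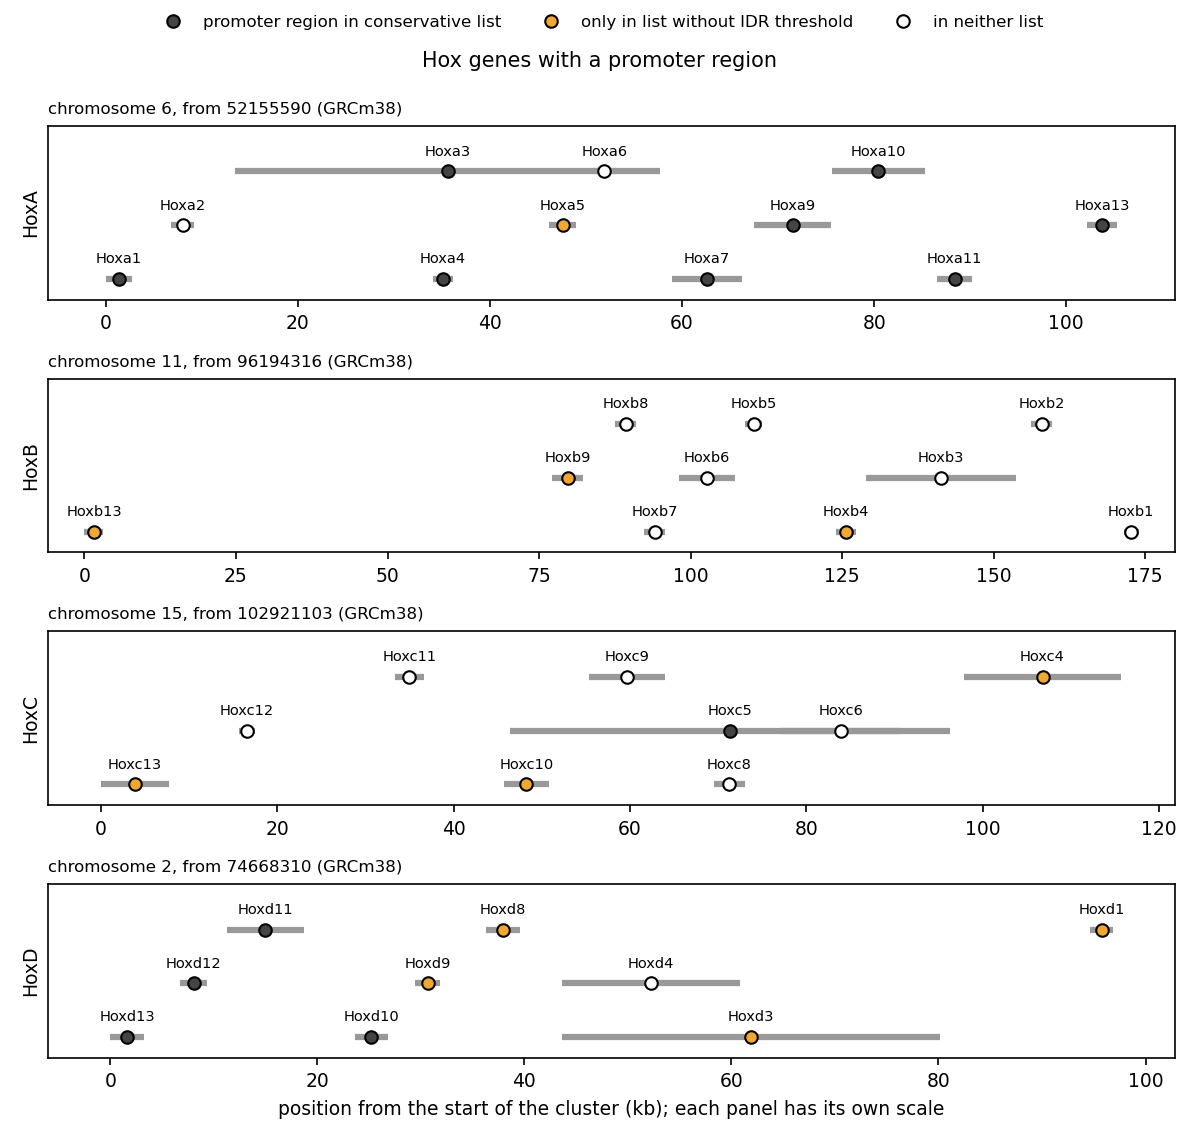
Maps of the 4 Hox clusters (horizontal axis, kb from the start of the cluster; grey bars, gene bodies), with a circle at each gene that is filled dark where the conservative list has a promoter region, orange where only the list without an IDR threshold has one, and open where neither has. Open promoters of the conservative list numbered 8 in HoxA, 0 in HoxB, 1 in HoxC and 4 in HoxD.

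Distal regions had their strongest summit over 1 kb from every protein-coding start site. They were more frequent around genes of skeletal muscle, of BMP, WNT and retinoic acid signalling and around housekeeping genes than around random genes with as much DNA nearest to their start sites. The 32 muscle genes had 34 distal regions within 100 kb (1.06 per gene against 0.372 in 10000 random lists, two-sided permutation test, adjusted p = 0.00480), with 5 around Mef2c, a transcription factor of muscle differentiation, and 2 around Cdh15, the muscle cadherin. BMP and TGF-beta genes had 32 (1.33 against 0.529, 0.0144), of which 8 were around Smad7, an inhibitor of the pathway, and 3 around its target Id1. WNT genes had 31 (1.24 against 0.514, 0.0252), with 3 each around Dkk3 and Tcf7l2, and retinoic acid genes had 20 (1.25 against 0.439, 0.0394), with 4 around the receptor Rxra and 3 around Rara. Housekeeping genes also exceeded the random lists (0.600 against 0.160, 0.0416), with 4 regions around Ywhaz, and chemosensory receptors lay below them (0.0171 against 0.181, 0.00480). The limb patterning list did not differ from random lists (21 regions, 0.600 against 0.533, permutation adjusted p = 0.953). Hand2 had 4 and Lmx1b 2. Nor did any of the other 17 lists, the lowest adjusted p being 0.325 for osteoblast markers, among which Col1a2 had 5 regions and Col1a1 4. Col2a1, the main collagen of cartilage, had 2 (2 in replicate 1 and 1 in replicate 2). The proteoglycan gene Acan had 1, found in neither replicate's own list, and the endothelial factor Erg 4. In total there were 8409 distal regions, 56.8% intergenic, 39.4% in introns and 3.83% in exons, and 6691 of them were given to 4315 genes. Of the 8409, 9.56% lay within 1 kb of a start site of a noncoding gene or pseudogene. In the lists of replicates 1 and 2 that share was 10.4% and 13.9%. The genes with most were 2010111I01Rik (12), Rgs3, a regulator of G-protein signalling (10), Tenm4, Trim27 and Usp29 (9 each), and Cstad, Dnm3, Frmd4a, Smad7 and Tgfbr3, a co-receptor for TGF-beta (8 each). The order differed in the replicates, where 2010111I01Rik had 7 and 3 regions, fewer than Rgs3 and Tgfbr3 (9 and 6 each). Tenm4 had 7 and 3, Trim27 8 and 3, Usp29 6 and 4, Cstad 5 and 3, Dnm3 6 and 4, and Frmd4a 5 in each. Smad7 had 6 and 4 regions in replicates 1 and 2, Mef2c 2 and 3, Dkk3 2 and 1, Rxra 4 and 2, Ywhaz 3 and 2, and Tcf7l2 and Erg 1 in each. None of the higher calls was made in replicate 2 alone, where adjusted p-values were 0.102 (muscle), 0.170 (BMP), 0.172 (WNT), 0.648 (retinoic acid) and 0.648 (housekeeping), or in the stronger 50% of regions. In replicate 2 the means were 0.438 per muscle gene against 0.162, 0.542 per BMP gene against 0.220 and 0.520 per WNT gene against 0.216, from 14, 13 and 13 regions. Replicate 1 alone gave muscle (0.00800), BMP (0.00240) and WNT (0.0324) but neither retinoic acid (0.210) nor housekeeping genes (0.134). Within 50 kb the BMP (0.0701) and housekeeping (0.209) calls were lost, as was retinoic acid in the other IDR list (0.211) and the housekeeping call without an IDR threshold (0.194) and without matching on stretch length (0.362).

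The 5 strongest distal regions were all intergenic and found in both replicates. The first lay 35531 bp from the start of Pak3, a kinase gene (X:143482936–143483180, signal 56.0), and the next 12986 bp from Abcb11 (2:69355470–69355735, 51.0). The others were nearest to G6pd2, at 1765841 bp (5:60042765–60043140, 41.0), Gm5426 (10:96077546–96077953, 38.8) and Frmd4a (2:3964426–3964690, 38.2). The regions nearest to Abcb11, G6pd2 and Gm5426 matched mitochondrial DNA over 129, 336 and 352 bp at 100%, 97.6% and 97.4% identity.

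The binding motif of CTCF, a factor at chromatin loop anchors, was enriched most at distal summits. It lay within 100 bp of 8.57% of the 8409 summits and in 0.387% of windows 1 kb away, a ratio of 22.2 (19.4 ± 0.566, SD, n = 2, over the replicates), and the highest ratio among 20 shuffled versions of the motif was 7.33. The E-box CAGCTG, bound by myogenic bHLH factors among others, lay at 32.1% of summits and in 9.84% of flanking windows. Its ratio was 3.27 (3.11 ± 0.107, SD, n = 2), with a highest shuffled ratio of 3.05, which the ratio in replicate 2 (3.04) did not exceed. For all motifs the shuffles were searched in the conservative list only, so no replicate ratio was compared with shuffles from its own list. The motif of TEAD factors had a ratio of 1.62 (1.58 ± 0.0271, SD, n = 2; highest shuffle 1.24), the SP or KLF motif 5.51 (shuffles up to 3.92), the NFI motif 7 (up to 4), the MEF2 motif of muscle genes 1.97 (up to 0.929) and the AP-1 motif 1.51 (up to 1.26). The TWIST or HAND E-box CATCTG (1.51) and the ETS motif (3.39) were also enriched against flanks. Both lay within the range of their shuffles, which reached 1.70 and 6, although the ETS ratio in replicate 2 (6.80) lay above. Motifs of GATA (0.394), homeodomain (0.434), PITX (0.730) and posterior HOX factors (0.922) were rarer at summits than in flanks. In the conservative list the first 3 lay within the range of their shuffles (0.372 to 0.965 for GATA, 0.286 to 0.606 for homeodomain, 0.489 to 1.02 for PITX). The GATA ratio in replicate 2 (0.296) lay below all GATA shuffles of the conservative list. Posterior HOX lay above all of its shuffles (highest 0.886), although its ratio in replicate 2 (0.867) lay below the highest shuffle of the conservative list. Motifs of RUNX (1.09), SOX (0.992), TP63 (1.05), GLI (1.37), PBX-HOX (0.843), TBX (0.851) and HNF4 (0.780) did not differ from flanks, and those of HNF1 and OCT4-SOX2 had no match. By an exact binomial test on summits that differed from their flanks, adjusted over 22 motifs, 9 were higher and 4 lower, with adjusted p-values of 9.17e-171 for CTCF, 1.91e-276 for CAGCTG and 0.0473 for posterior HOX. The NFI, ETS and MEF2 ratios rested on few summits: the motifs lay at 0.167%, 0.262% and 0.666% of them, against 16.7% for TEAD. Summits with the motif and without it in the drawn flank numbered 14 for NFI (3 the reverse), 22 for ETS (6) and 55 for MEF2 (26). The NFI ratio was 12 in replicate 1 and 7 in replicate 2, the MEF2 ratio 1.25 and 1.93, and the ETS ratio 4.17 and 6.80. Over the alternatives that gave a ratio it ranged from 7 to 19 for NFI, 1.17 to 2 for MEF2, 1.54 to 14 for ETS, 3.50 to 11.6 for SP or KLF and 18.7 to 39.1 for CTCF. The GC content was 54.1% at summits and 46.1% in flanks. The MEF2 (binomial adjusted p = 1 in replicate 1 and 0.0901 in replicate 2) and posterior HOX (0.233 and 0.0717) calls were lost in each replicate's own list and the AP-1 call in replicate 2 (0.0537). AP-1 (0.390) and MEF2 (0.504) were lost in the stronger 50%, MEF2 (0.0568) and NFI (0.550) in windows of 50 bp, posterior HOX in the other IDR list (0.382) and ETS without an IDR threshold (0.196). RUNX and GLI motifs became enriched without an IDR threshold (6.30e-06 and 1.53e-09), SOX in replicate 1 alone (ratio 1.16, 0.0361), PBX-HOX fell below flanks in windows of 50 bp (0.0309) and TBX against flanks 2 kb away (0.0201).

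**Figure D4:**
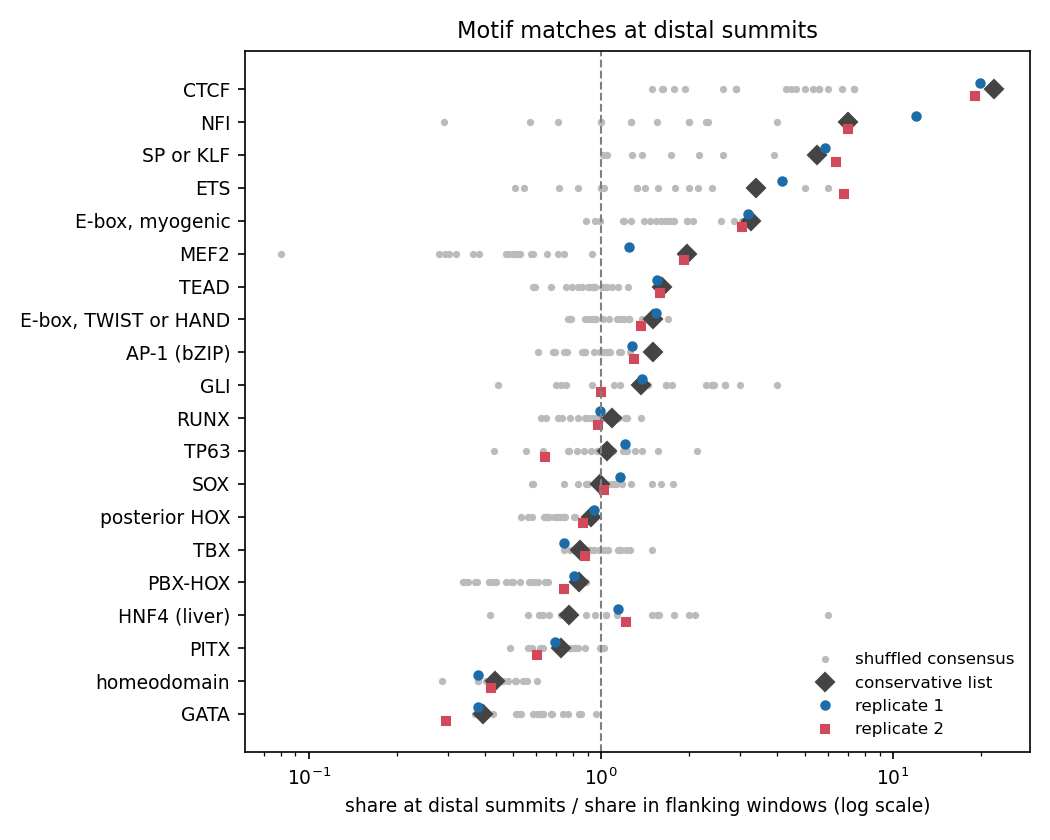
Ratio of the share of distal summits with a motif to the share of flanking windows with it (horizontal axis, logarithmic; diamonds, conservative list; circles and squares, replicates 1 and 2; grey points, shuffled motifs), with a dashed line at 1. In the conservative list CTCF (22.2) and CAGCTG (3.27) lay above all of their shuffles, and GATA (0.394) and homeodomain motifs (0.434) lay below 1 and within the range of theirs. GATA in replicate 2 (0.296) lay below the GATA shuffles, which were searched in the conservative list only.

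The X chromosome held fewer open regions per length than the autosomes in both replicates. In replicate 1 it had 2.77 regions per Mb against 7.05 on autosomes (ratio 0.392), and in replicate 2 2.32 against 5.21 (ratio 0.444). Of the X-linked protein-coding genes, 379 of 948 had a promoter region (40.0%), against 54.5% of autosomal genes. Of 183 genes of the Y chromosome 3 did. The pools were of both sexes, and in the lists without an IDR threshold the ratios were 0.317 and 0.336.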

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

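For these patterns the tests against mitochondrial DNA, against a removal of peaks and against the IDR threshold were chosen after the result was seen, and those on second copies, base composition, repeated sequence and CpG content before. The samples form a single group, so no biological explanation was tested for any of them.

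A signal lay in data that the comparisons did not use. The ranked list that contains the conservative list held 190 summits with a score of at least 540 that the conservative list lacks, in 72 intervals and with signals up to 48.3. Of these summits 44 lay on unplaced or unlocalized scaffolds and 146 on chromosomes.

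The 5 strongest distal regions were all intergenic, and the one nearest to G6pd2 lay 1765841 bp from the nearest protein-coding start site. Of the 50 strongest distal regions 7 matched mitochondrial DNA, against 6 of the other 8359 (one-sided Fisher's exact test, p = 2.84e-13), so nuclear copies of mitochondrial DNA are a candidate explanation for those 7. It was not considered for the other 43, which were set apart by their lack of a match. Near-identical copies elsewhere in the nuclear genome cannot be told apart from other explanations for the 43: 6.98% of them had a second locus of 95% identity over 80% of the region, against 2% of 200 other distal regions (two-sided Fisher's exact test, p = 0.108), and copies collapsed into one in the assembly cannot be seen.

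The E-box CAGCTG was more frequent at distal summits than beside them. Summits with the motif and flanks without it outnumbered the reverse 4.37-fold (95% interval 3.98–4.80). In 1173 summits whose flanks had a GC content within 2 points the ratio was 3.16 (2.51–4.02), and in 400 summits without a repeat-masked base it was 3.08 (2.14–4.51). Both argue against base composition or repeated sequence as the whole cause, although the ratio fell in both subsets. In the 81 summits that met both conditions it was 2.88 (1.24–7.43).

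No HoxB promoter had a region in the conservative list. Random lists matched on the CpG content of these promoters had a region at 61.8% of members on average, which argues against CpG content alone as the cause. Of these lists 0 of 10000 had none. Their members were drawn singly from across the genome, whereas the HoxB genes are neighbours. How often neighbouring genes would all lack a region was therefore not measured. Removal of peaks between the ranked and the thresholded list was also argued against, since 0 HoxB genes had a ranked summit past a score of 540 within 1 kb of a start site. The IDR threshold stays open: without it 3 of 10 HoxB and 9 of 11 HoxA promoters had a region, and with so few genes this difference (Fisher's exact test, two-sided, adjusted p = 0.0899) cannot be told apart from no difference.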

How the results depend on the processing

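Apart from counting every summit and leaving out the regions that match mitochondrial DNA, which were chosen after the results were seen, the alternatives were chosen before. No paired analysis was possible because the samples form 1 group without a contrast. Leaving out the matching regions changed none of the 99 distal and motif results it was run on. Over all alternatives 66 values of the main results stayed within a limit set for their kind and 49 moved. For the promoter share the limit was the SD over the replicates, and for counts of genes and lists a fixed ratio. Among values per gene, list or motif 1878 stayed the same, 290 moved and 86 changed direction, 76 of them where neither value passed the threshold. Of all tested values 53 lost and 19 gained a call. The cause was not tested, except that unmerged, pseudoreplicated or replicate lists differ in size by construction. Unmerged lists had 41240, 30696 and 47946 entries and pseudoreplicated lists 50490 and 38915 regions. The overlap of replicate 1 in 2 and of 2 in 1 was 66.6% and 89.8% if 50% of both regions had to be shared, 61.0% and 80.6% in pseudoreplicated lists, 82.3% and 83.1% at equal number, and 71.5% and 96.5% in the stronger 50%. In pseudoreplicated lists it was 21.4% and 45.8% for the weakest 10% and 99.98% for the strongest 10% of replicate 1, and the X to autosome ratios were 0.317 and 0.336. The promoter share was 26.7% without an IDR threshold, 81.1% in the stronger 50% and 60.8% to 72.8% without either replicate.

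Coverage of HoxA, HoxB and HoxC was 8.35%, 0.285% and 1.70% in the other IDR list. In the list without an IDR threshold HoxA, HoxB, HoxC and HoxD had 11.2%, 1.29%, 4.64% and 8.53%, and in the stronger 50% all had 0. Leaving out either replicate gave 4.65% to 5.63% (HoxA), 0 to 0.142% (HoxB), 0 to 0.809% (HoxC) and 1.20% to 2.31% (HoxD).

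The number of lists with open promoters more often was 1 with a window of 500 bp, 0 with CpG matching, 5 without an IDR threshold (6 less often), 1 in the stronger 50% (18 less often, against 12 in the conservative list) and 1 without either replicate. Differences from other genes that changed direction are given in points. In the stronger 50% limb patterning had −26.3, HoxA −40.5, BMP −11.4 and WNT −16.5. With CpG matching limb patterning had −24.7, HoxA −12.7, WNT −19.1, osteoblast 5.32, muscle 11.1 and Schwann cell 7.10. Without an IDR threshold HoxD had 25.5, retinoic acid 5.38, chondrocyte 11.6, joint and tendon 22.4, muscle 21.04 and neuron 3.30. In the other IDR list limb patterning had −0.0825, retinoic acid 1.88 and joint and tendon 2.78. With a window of 2.5 kb retinoic acid had 13.8, joint and tendon 2.20 and muscle 4.44, and with 500 bp limb patterning had −5.82 and muscle 1.60. With 1 start site per gene limb patterning had −12.7 and WNT −1.82, and with every summit retinoic acid and muscle each had 2.47. Leaving out either replicate gave limb patterning −12.6 to −6.15, WNT −14.9 to 0.143 and joint and tendon −4.01 to 5.29.

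Lists with more distal regions than random lists numbered 3 within 50 kb, 0 in the stronger 50%, and 0 to 3 without either replicate. Differences per member that changed direction follow. In the other IDR list HoxA had 0.0939, HoxB 0.0614, HoxC 0.0514, chondrocyte 0.288, epidermis 0.134 and cardiomyocyte 0.0602. Without an IDR threshold HoxA had 0.712, HoxB 0.124, HoxC 0.279, HoxD −0.0170, chondrocyte 1.04, epidermis 0.0695, myeloid −0.0519, cardiomyocyte 0.0267 and germ cell −0.116. In the stronger 50% limb patterning had −0.0552, HoxD −0.0165, retinoic acid −0.0947, joint and tendon −0.0119, epidermis 0.114, erythroid 0.00921, neuron 0.0161 and cardiomyocyte 0.00114. Hepatocyte had 0.00602 within 1 Mb and 0.0156 within 50 kb. Without matching on stretch length HoxD had −0.195, chondrocyte 0.0122 and lymphoid −0.0583. Leaving out either replicate gave HoxA −0.0387 to 0.113, HoxD −0.0624 to −0.0361, chondrocyte −0.00110 to 0.0628, epidermis 0.0916 to 0.115, myeloid −0.0529 to 0.0232 and cardiomyocyte 0.00226 to 0.0184.

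Motif ratios that crossed 1 were SOX 1.06 in the other IDR list and 1.07 in windows of 50 bp, and TP63 0.976 with flanks 2 kb away. Without an IDR threshold they were posterior HOX 1.001, TP63 0.969, PBX-HOX 1.01 and TBX 1.03, and in the stronger 50% RUNX 0.924, SOX 1.01 and HNF4 1.43. Leaving out either replicate gave RUNX 0.976 to 0.994, SOX 1.03 to 1.16, TP63 0.645 to 1.21 and HNF4 1.14 to 1.22. The read depth is unknown, so what depth limits could not be measured.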

Other observations

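Distal regions around skeletal muscle genes were tested for the E-box CAGCTG, which the myogenic bHLH factors bind, and this test was chosen before its result was seen. The hypothesis was that the E-box is more frequent there than in other distal regions. It lay at 16 of the 34 summits (47.1%) against 32.0% of other distal summits, a difference that did not pass (Fisher's exact test, two-sided, p = 0.0671). In replicate 1 the shares were 53.6% (15 of 28) and 31.6% (exact p = 0.0229). In replicate 2 they were 28.6% (4 of 14) and 29.6% (exact p = 1), and without an IDR threshold 29.8% (42 of 141) and 30.7% (p = 0.855). The hypothesis stays open, since the summits are few and the lists differ. No biological explanation beyond it was tested.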
